A study of Rattus norvegicus with 6 samples.

How the data were processed

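Polyadenylated RNA of cultured rat ventricular fibroblasts was sequenced as paired-end reads of 150 bp, per the labels' protocols, in 3 NC and 3 antagomiR libraries. Per the labels, cDNA was made with a NuGEN Ovation kit and libraries with a TruSeq kit. The submitters' processing notes name FastQC, cutadapt, HISAT2, HTSeq and edgeR, with no versions, and the build mRatBN7.2. The order of these steps, the annotation release and the strand setting were not given in the sources used here. The deposited table held FPKM, which are fragment counts scaled to gene length and library total, for 30560 genes with symbols, coordinates and one column per library. Without a stated strand setting, overlapping and antisense genes and near-identical copies cannot be told apart. Some broadly expressed genes are listed at or near 0, so such a value may not show the level in the cells.

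Columns were assigned to groups by the names in the labels, and 0 columns of per-sample values were left unassigned. The depth was recovered from the FPKM values, because each value is a whole number of fragments divided by the gene's length and the library total. Short genes, under 400 bp, gave the library totals, and a length that made all 6 values whole within 0.01 was found for 100% of the 20134 genes above 0. The recovered fragments made up at least 99.7% of each total. On simulated data 6 library totals and the counts of 99% of 3000 genes were recovered exactly. Totals ran from 19472409 to 24622667 fragments, and mitochondrial genes took 3.5% of them in NC replicate 3 to 4.5%. Of the tested genes 143 had fewer than 10 fragments on average, and their values are the least precise. Between replicates the chi-square per degree of freedom ran from 3.53 to 31.62, above sampling noise, so no library was treated as a repeat of another.

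The main test was limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend) on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 6 libraries. It was two-sided, with Benjamini-Hochberg adjusted p under 0.05 and without a replicate block. Fold changes are antagomiR minus NC on that scale. In a simulation of this comparison with 12024 genes, 200 of them changed, limma called 78.5% of genes changed 1.5-fold and 100% of those changed 2-fold or 4-fold. There 16 of 202 called genes were not changed. The simulation drew genes independently, with the same dispersion (spread beyond sampling noise) of 0.01 for all and no library set apart. These rates may therefore not hold for the real libraries. Of 44 gene lists written before the data were examined, 43 had at least 3 tested members and were tested with limma camera, with a preset correlation of 0.01 and adjustment over the lists.

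Named genes were chosen by a rule set before the data were examined. It took Mir142, then up to 12 genes in each direction with the largest log2 fold change among called genes with a symbol and groups whose ranges did not overlap. It added the members of the list of reported targets, and up to 4 members with the smallest p from each list described. Il33, Lyz2, Mrc1, C1qa and C1qb fell outside the rule and were named after their values were seen.

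Alternatives set before the data were examined were pseudocounts of 0.1 and 0.01, no filter, filters at 0.1 and 5 FPKM, median-ratio scaling, quantile normalization, a replicate block, limma without a trend, with array weights and with robust variances, and leaving out each library. For lists, camera with an estimated correlation and fry were added, and for genes a 2-fold minimum. Limma voom on the recovered fragment counts and a covariate of leukocyte marker expression were chosen after seeing the data. A planned comparison of genes with and without a miR-142-3p seed site was not run, because it needs 3' UTR sequences and no genome sequence was used here.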

Results

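RNA was sequenced from primary cardiac fibroblasts of newborn rats after transfection with an antagomiR against miR-142-3p or with a negative control oligonucleotide (NC). An antagomiR is a chemically modified antisense oligonucleotide that binds and blocks a mature microRNA. The cells came from ventricles of Sprague-Dawley pups aged 1 to 2 days, were enriched by preferential attachment and starved of serum overnight, and received 50 nM of either oligonucleotide. Each group had 3 libraries, and the labels did not say whether these came from separate cell isolations, so p-values measure only the spread between these libraries. Totals recovered from the FPKM values were 19472409, 24248843 and 19699443 fragments in NC replicates 1, 2 and 3. The antagomiR replicates 1, 2 and 3 had 22215475, 24622667 and 22853865 fragments. At these totals 3 fragments on a gene of 1 kb corresponded to between 0.122 and 0.154 FPKM, a floor that covers counting error only. Of 30560 genes in the table, 12024 had a mean of at least 1 FPKM over the 6 libraries and were tested.

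The transcript of the microRNA's own gene was examined first. Mir142 (ENSRNOG00000035633) is listed on chromosome 10 from 72557857 to 72557967 in mRatBN7.2, and the 111 bp feature is the precursor. Its values were 2.78, 1.11 and 1.37 FPKM in NC replicates 1 to 3, from 6, 3 and 3 fragments. They were 2.84, 1.83 and 3.15 FPKM in antagomiR replicates 1 to 3, from 7, 5 and 8 fragments. The log2 fold change was 0.42 with a standard error of 0.24 (limma adjusted p = 0.25). Without NC replicate 1 it was called up, at 0.67 (adjusted p = 0.0442), so the outcome at this depth rests on 1 library. An antagomiR acts on the mature microRNA, which polyA libraries do not measure, and these values therefore did not check whether miR-142-3p was silenced.

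The comparison of antagomiR with NC asked which transcripts of the cardiac fibroblast cultures differed when miR-142-3p was targeted. The cultures also held leukocyte transcripts, so a change is not assigned to a cell type. Of the fixed gene lists tested, that of inflammatory cytokines and chemokines had the highest median log2 fold change and that of cholesterol and fatty acid synthesis the lowest. Pla2g2a, a secreted phospholipase, went from 0.388 ± 0.416 FPKM in NC to 142 ± 19.9 FPKM with the antagomiR (SD, n = 3). The neutrophil-attracting chemokine Cxcl1 went from 1.7 ± 0.546 to 174 ± 19 FPKM, and the monocyte chemokine Ccl2 from 69.1 ± 39 to 1305 ± 52.6 FPKM. Eln, which encodes elastin, fell from 924 ± 49.5 to 329 ± 1.21 FPKM, and Tgfb3, a transforming growth factor, from 680 ± 51.8 to 256 ± 7.58 FPKM. In all, 2109 genes rose and 1107 fell by limma on log2(FPKM + 1) at an adjusted p under 0.05, and 460 of the risen and 64 of the fallen genes changed at least 2-fold. The groups' ranges did not overlap for 44.6% of tested genes, where chance gives 10%. The share of risen among called genes was 65.6%, against 51.5% after median-ratio scaling and 43.1% after quantile normalization, which moved the median log2 fold change of all genes by -0.11. The count of 3216 called genes became 4862 without NC replicate 3, and 2033, 2000 and 1883 without antagomiR replicate 1, 2 or 3.

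The 12 largest rises, on the log2(FPKM + 1) scale that understates changes of low genes, ran from 4.25 for C1s to 6.73 for Pla2g2a. Beside these and Cxcl1 at 6.03 stood the chemokine genes Ccl12 at 6.39, Cxcl3 at 5.49, Ccl7 at 5.45 and Ccl2 at 4.36. The complement genes C3 at 5.44 and C1s, the cytokine Il1b at 4.46 and Vcam1 at 4.28, an adhesion molecule for leukocytes, were also among them. Lcn2, an iron-carrier binding protein, rose by 5.69, and Enpp2, which encodes the enzyme autotaxin, by 4.39. Limma adjusted p was between 7.25e-07 for Lcn2 and 0.00029 for C3. Pla2g2a (ENSRNOG00000016945) lies on chromosome 5 from 151076442 to 151079014, and Cxcl1 on chromosome 14 from 17193365 to 17195215.

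The 12 largest falls were smaller, between -2.17 for Nefm, a neurofilament gene, and -1.40 for Tgfb3. Scd, a fatty acid desaturase, fell by 1.71, Tnc, the matrix glycoprotein tenascin C, by 1.55 and Eln by 1.49. The others were Prss35 at -1.84, Metrn at -1.60, the chemokine receptor gene Cxcr4 at -1.54, Gldn at -1.48 and Ighm at -1.42. The size of the fall of Cxcr4 rests in part on NC replicate 3, with 3.7, 3.89 and 10.1 FPKM in NC replicates 1 to 3. Limma adjusted p was 2.09e-05 for Eln, which lies on chromosome 12 from 21968544 to 22011928. Apoe, at -1.66 with an adjusted p of 0.031, was at 124, 158 and 455 FPKM in NC replicates 1 to 3 and fell by 1.09 without NC replicate 3. It lost its call in 6 alternative fits, among them those without NC replicate 2 (adjusted p = 0.0568) and without antagomiR replicate 1, 2 or 3 (0.0768, 0.0997 and 0.0934). SNORD24, at -1.82, is a small nucleolar RNA shorter than a sequenced fragment, so its value is uncertain, and its call was lost with a pseudocount of 0.01, at -4.63 (adjusted p = 0.0674), and with the leukocyte covariate, at -1.29 (adjusted p = 0.057).

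**Figure D1:**
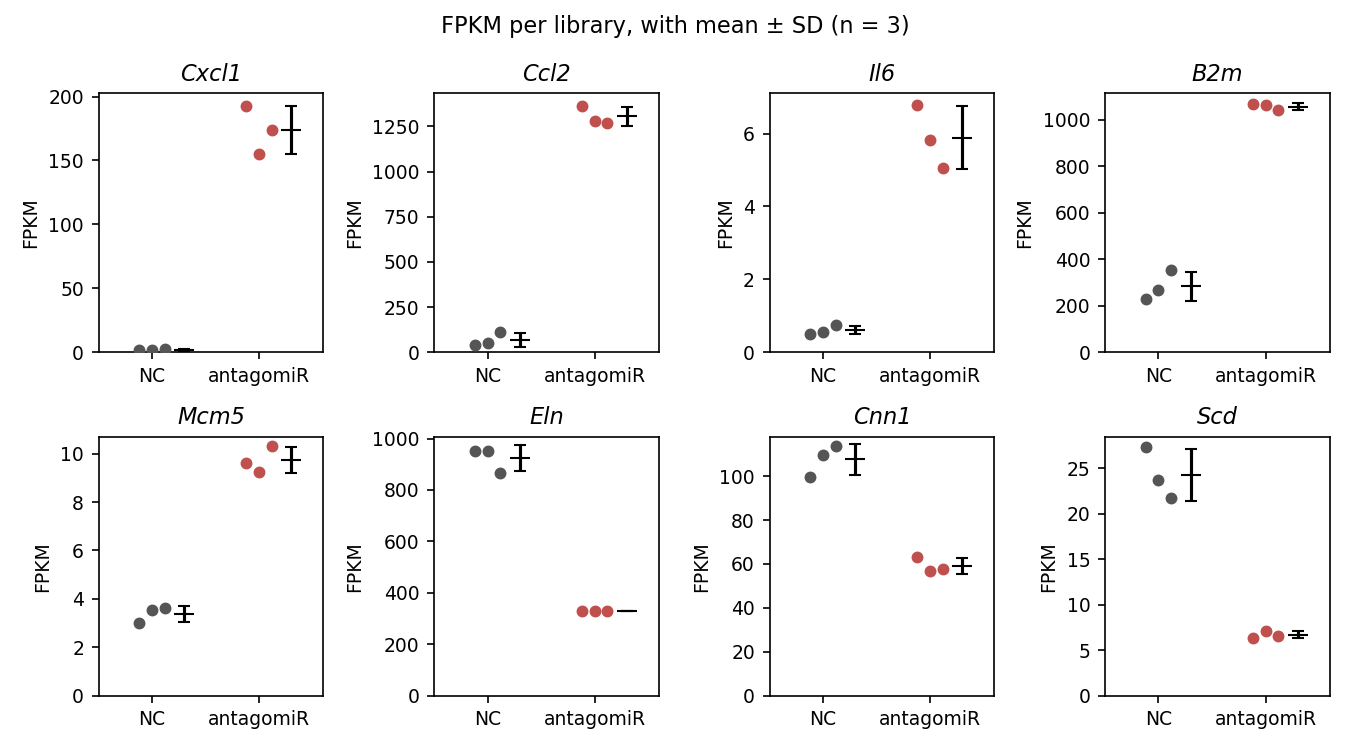
FPKM (linear axis from 0) of 8 genes in each of the 3 NC and 3 antagomiR libraries, with bars for mean ± SD. Cxcl1, Ccl2, Il6, B2m and Mcm5 were higher and Eln, Cnn1 and Scd lower in each antagomiR library than in each NC library.

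Inflammatory signalling genes rose as a group. Of 22 tested inflammatory cytokine and chemokine genes, 20 rose and 1 fell, with a median log2 fold change of 2.57, and the counts adjusted over the list alone were the same. The median was 4.37 with a pseudocount of 0.1, 4.52 with 0.01 and 4.43 by voom, since many members were near 0 in NC. Cxcl6 went from 0.0298 ± 0.0297 to 11.2 ± 1.18 FPKM and Il6 from 0.602 ± 0.117 to 5.88 ± 0.863 FPKM (SD, n = 3), whereas Il33, a cytokine stored in nuclei, fell from 5.16 to 2.63 FPKM. Of 20 tested NF-kB pathway genes, 17 rose and none fell, or 19 adjusted over the list alone. They included the feedback inhibitors Tnfaip3, with a log2 fold change of 2.35, Tnip1 at 1.79 and the nuclear regulator Nfkbiz at 2.40. Limma camera with a preset correlation of 0.01 called the lists with adjusted p = 4.51e-15 and 3.5e-10. With an estimated correlation the adjusted p was 0.127 for the cytokine list and 0.217 for the NF-kB list.

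Interferon response and antigen presentation genes rose as well. Of 26 tested interferon response and RNA sensing genes, 25 rose and none fell, with a median log2 fold change of 1.73, and all 26 rose when adjusted over the list alone. Ifit3 went from 0.765 ± 0.699 to 10.7 ± 0.772 FPKM, the guanylate-binding protein gene Gbp2 from 1.54 ± 0.851 to 13.7 ± 1.77 FPKM, and Irf1, a transcription factor, from 4.42 to 9.6 FPKM. Of 7 tested antigen presentation genes 6 rose, over all genes and adjusted over the list alone, among them B2m, the light chain of class I molecules, from 283 ± 62.1 to 1056 ± 14 FPKM. The other members, among them class II genes, lay below the filter or were not analysed here, and with no filter the median of the antigen presentation list went from 1.12 to 0.35. Camera gave adjusted p = 4.03e-11 and 0.00325, and with an estimated correlation the adjusted p was 0.355 and 0.488. Several interferon genes of the fixed list were not analysed here.

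Leukocyte markers moved with these groups and also set NC replicate 3 apart. Of 15 tested leukocyte markers 6 rose, or 9 adjusted over the list alone, with a median log2 fold change of 1.17 (camera adjusted p = 0.0243, and adjusted p = 0.779 with an estimated correlation). Lyz2, the most abundant of them, was at 62.7, 105 and 390 FPKM in NC replicates 1, 2 and 3 and at 566, 484 and 520 FPKM in the antagomiR replicates. Adgre1, a macrophage receptor, was at 1.3, 3.37 and 11.4 FPKM in NC and 55, 59.3 and 63.3 FPKM with the antagomiR. The markers did not rise alike, and 9 of the 15, Lyz2 among them, were not called. The macrophage genes Mrc1, C1qa and C1qb had 0.944, 1.01 and 0.976 times their NC mean with the antagomiR, and 1.7, 1.59 and 1.63 times without NC replicate 3, where Adgre1 had 25.31 times. All 15 were higher in NC replicate 3 than in NC replicates 1 and 2. The leukocyte call was lost without NC replicate 1 (adjusted p = 0.123) and without NC replicate 2 (adjusted p = 0.0713), and fry did not call the list (adjusted p = 0.28). All 15 rose without NC replicate 3, with a median of 1.86. Without NC replicate 3, 20 cytokine, 19 NF-kB, 26 interferon and 6 antigen presentation genes rose. Along the first principal component, with 77.2% of the variance, NC replicates 1, 2 and 3 lay at -36.1, -30.9 and -13.8 and the antagomiR replicates between 26.3 and 27.3.

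**Figure D2:**
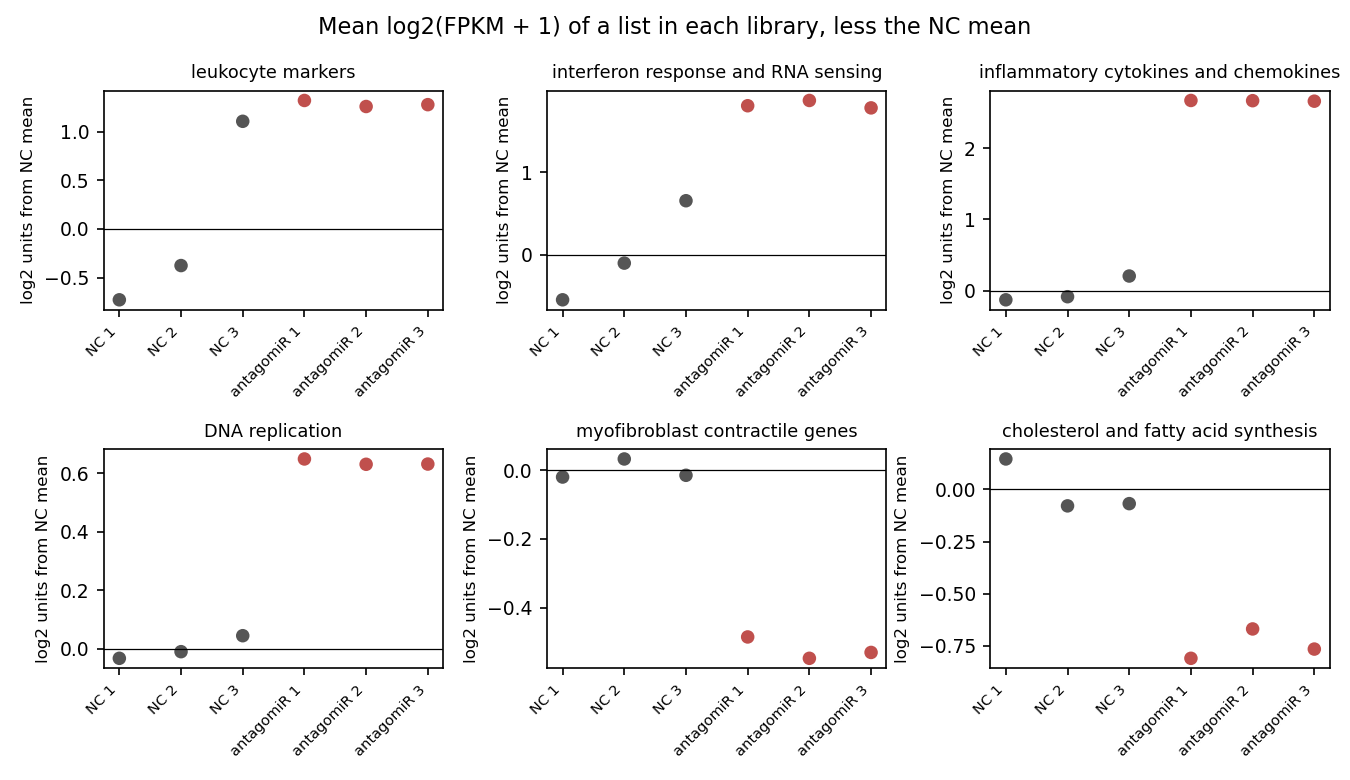
Mean log2(FPKM + 1) of the tested members of 6 fixed gene lists in each library, in log2 units from the NC mean, with a separate vertical scale per panel. NC replicate 3 stood at 1.11 for leukocyte markers, near the antagomiR libraries at 1.26 to 1.32, but at 0.208 for inflammatory genes, where the antagomiR libraries stood at 2.66 to 2.67.

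Contractile genes of myofibroblasts, the activated and contractile state of fibroblasts, fell together. Of 20 tested members 18 fell and none rose, over all genes and adjusted over the list alone, with a median log2 fold change of -0.57. The smooth muscle calponin gene Cnn1 fell from 108 ± 7.2 to 59.2 ± 3.63 FPKM, the tropomyosin gene Tpm1 from 512 ± 27.4 to 312 ± 9.23 FPKM, and Myl9, a myosin light chain gene, from 632 ± 23.7 to 395 ± 18.7 FPKM. Of 15 YAP and SRF targets 6 fell and none rose, among them Ankrd1 by 0.67 on the log2 scale. Of 19 integrin and focal adhesion genes 7 fell and none rose, led by Itga6, at -0.99, and Itgb1 fell from 1025 to 683 FPKM. Counts adjusted over each list alone were again 6 and 7. Camera adjusted p was 7.23e-15, 8.89e-05 and 0.000141, and with an estimated correlation the adjusted p was 0.117, 0.205 and 0.117. Without NC replicate 3, 18, 7 and 9 members fell. Smooth muscle and pericyte markers fell as well (5 of 9, with 1 risen; camera adjusted p = 0.014, and adjusted p = 0.205 with an estimated correlation), and Cnn1 and Myl9 are also expressed in smooth muscle. With no filter or a minimum of 0.1 FPKM that list was not called and its median was 0.11 (adjusted p = 0.272 and 0.201).

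Matrix genes moved in both directions. Of 19 collagen genes 5 rose and 7 fell, over all genes and adjusted over the list alone, and camera did not call the list (adjusted p = 0.0813). Col6a1 rose from 222 to 408 FPKM, while Col12a1 fell from 34.1 to 21.1 FPKM. Of 24 matrix glycoprotein and proteoglycan genes 6 rose and 9 fell, or 8 and 10 adjusted over the list alone, without a call (adjusted p = 0.194). The median of that list was -0.09 and its mean 0.05, while camera gave its direction as down. Thbs2, a thrombospondin gene, rose by 1.89 and Fbln1, which encodes fibulin 1, by 2.21. Both lists were called down without NC replicate 3 (adjusted p = 0.0338 and 0.0477). Collagen processing and crosslinking genes were called down (adjusted p = 4.42e-05, and adjusted p = 0.117 with an estimated correlation). There 9 of 15 fell and 1 rose, with 10 falling when adjusted over the list alone. The crosslinking enzyme gene Lox fell from 458 ± 60.9 to 253 ± 4.29 FPKM and P4ha2, a collagen hydroxylase subunit gene, rose from 79.7 to 154 FPKM. In the TGF-beta list 10 of 21 fell and 3 rose, over all genes and adjusted over the list alone (adjusted p = 0.000306, and adjusted p = 0.205 with an estimated correlation). The co-receptor gene Tgfbr3 rose by 0.94.

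Genes of cholesterol and fatty acid synthesis fell. Of 22 tested members 20 fell and none rose, or 21 adjusted over the list alone, with a median log2 fold change of -0.73 (camera adjusted p = 7.59e-17, and adjusted p = 0.217 with an estimated correlation). Scd fell from 24.3 ± 2.86 to 6.68 ± 0.375 FPKM. Cyp51, a sterol demethylase gene, fell from 104 to 53.4 FPKM, and Mvd, of the mevalonate pathway, from 19.5 to 11.6 FPKM. There were 21 that fell without NC replicate 3.

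Proliferation genes rose. Of 23 DNA replication genes 21 rose and none fell, and all 23 rose when adjusted over the list alone, with a median log2 fold change of 0.57. Mcm5, part of the replicative helicase, went from 3.38 ± 0.332 to 9.73 ± 0.544 FPKM, and Rrm2, a subunit of ribonucleotide reductase, from 6.12 ± 0.233 to 13.4 ± 0.824 FPKM. Of 26 cell cycle and mitosis genes 16 rose and 1 fell, or 19 and 1 adjusted over the list alone, among them the proliferation marker Mki67 from 2.9 ± 0.306 to 7.88 ± 0.323 FPKM. Camera adjusted p was 9.69e-10 and 0.000126, and with an estimated correlation the adjusted p was 0.0895 and 0.277. Without NC replicate 3, 23 replication and 16 cell cycle genes rose.

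**Figure D3:**
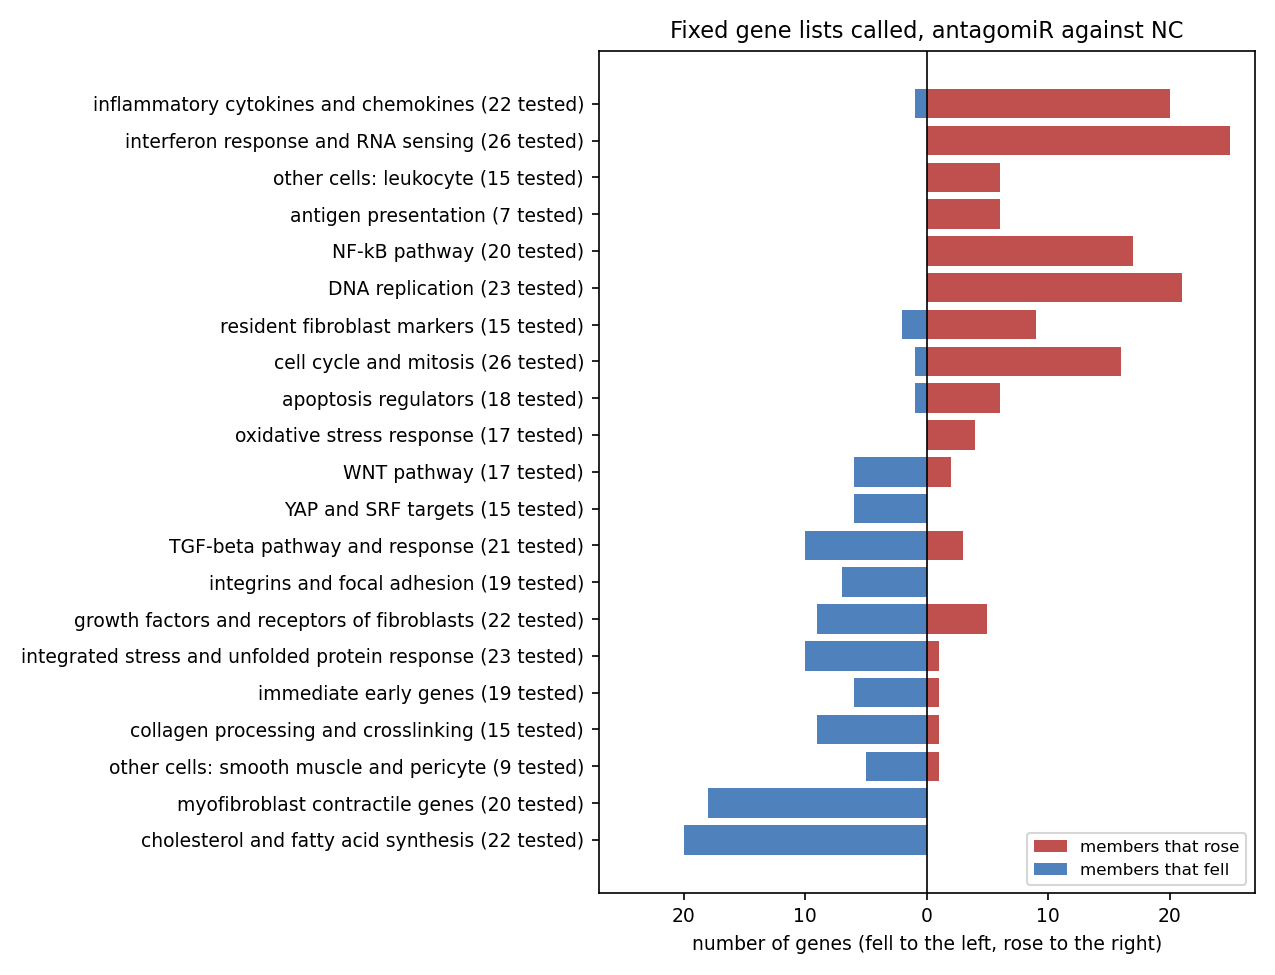
Number of members that fell (bars to the left) and rose (bars to the right) in each of the 21 fixed gene lists called by camera, ordered by median log2 fold change. The cholesterol and fatty acid synthesis list stood at one end with 20 of 22 falling, and the inflammatory list at the other with 20 of 22 rising.

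Reported targets of miR-142-3p were not called as a group by camera, but were by fry (adjusted p = 0.0248). Of 14 tested members 3 rose and 1 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.02 (camera adjusted p = 0.726). The risen genes were Il6, by 2.10, the receptor subunit gene Il6st, by 0.41, and the clock gene Arntl, by 0.41, and the actin-binding cofilin gene Cfl2 fell by 0.45. Il6st lost its call without antagomiR replicate 2 or 3 (adjusted p = 0.0655 and 0.0669). The log2 fold changes of the other 10 were -0.08 for Adcy9, 0.01 for Tab2, -0.01 for Tgfbr1, 0.0043 for Hmgb1, 0.07 for Itgav, -0.05 for Wasl, 0.03 for Twf1, -0.01 for Rac1, 0.17 for Ep300 and 0.16 for Rock2. With expression of leukocyte markers as a covariate, an alternative chosen after the results were seen, Tab2 (0.29), Ep300 (0.33) and Rock2 (0.41) were called up and Tgfbr1 (-0.34) down. Il6 is also a member of the cytokine list. The Hmgb1 entry tested lies on chromosome 16, with means of 1.68 FPKM in NC and 1.67 FPKM with the antagomiR. Since near-identical copies cannot be told apart, its value may not show the reported target itself.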

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

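The voom fit and the leukocyte covariate were chosen after the results were seen. The planned seed site comparison and its alternatives were not run for lack of 3' UTR sequences. The count of called genes, 3216, lay between 2380 and 3418 in the fits with another pseudocount, filter, scaling, block, trend or variance setting and in those 2 added fits, and rose to 7419 (4904 up, 2515 down) with array weights. The weights did not converge and gave NC replicate 2 a weight of 14 and NC replicate 3 one of 0.143, so that count is not relied on. Requiring a 2-fold change left 524. Leaving out 1 library gave 1883 to 4862 called genes, 1216 to 3185 risen and 667 to 1677 fallen. Those fits have fewer libraries, yet the highest count came without NC replicate 3. Quantile normalization gave 1869 fallen genes. With it 76.9% of the called genes were called in the same direction, and with median-ratio scaling 83.4%. Voom on recovered fragments called 3308 genes and shared 86.6% of the main calls. The cause of these differences was not tested.

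The labels do not say whether equal replicate numbers mark a shared preparation. Deviations from the group mean correlated at -0.16, -0.06 and -0.04 for equal numbers and between -0.06 and 0.13 for unequal ones. With 3 libraries per group and NC replicate 3 set apart, these values cannot decide it. With the replicate block 2380 genes and 21 lists were called. The count of called lists, 21, was 16 to 25 without 1 library and 0 with an estimated correlation, where the smallest adjusted p was 0.0895. Fry, which asks whether a list's genes move on balance one way, called 24. The leukocyte covariate kept 15 of the 21 list calls. With it the leukocyte list had a median of 0.03, as its construction requires, and the mitochondrially encoded list went from 0.08, not called, to 0.27. Tab2 was called at -0.11 with array weights and at 0.29 with the leukocyte covariate. Fabp4, at -0.24 and not called, ran from -0.84 to 0.86 when 1 library was left out, the latter without NC replicate 3 and called, and was called at -2.74 with the covariate. Over pairs of a named gene and a setting, 3409 kept direction and side of the threshold, 192 lost the call and 39 gained it, and for lists these numbers were 763, 35 and 15. Depth limits the low genes most, as for Mir142 with 3 to 8 fragments, called at 0.77 with array weights.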

Other observations

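Other fixed lists held changes not described above. Among growth factors and receptors of fibroblasts 5 of 22 rose and 9 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0243, and adjusted p = 0.375 with an estimated correlation). The median of that list was -0.15 and its mean 0.0093. This call was lost with median-ratio scaling, quantile normalization, voom, the leukocyte covariate and fry (adjusted p = 0.0558, 0.176, 0.0652, 0.396 and 0.356) and without NC replicate 1 (adjusted p = 0.0645). Igfbp3, a binding protein of insulin-like growth factors, rose from 22.6 ± 2.33 to 126 ± 12.4 FPKM and Pdgfra, a receptor of resident fibroblasts, from 8.54 ± 1.2 to 27.5 ± 0.149 FPKM, while Fgf2 fell from 14.8 to 8.11 FPKM. Of 15 resident fibroblast markers 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (adjusted p = 0.0351, and adjusted p = 0.277 with an estimated correlation), among them Dpep1, Dpt and Dcn. That call was lost without NC replicate 1 (adjusted p = 0.0548), with array weights (0.101) and with the leukocyte covariate (0.145). Of 9 smooth muscle and pericyte markers 5 fell and 1 rose, or 5 and 2 adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.205 with an estimated correlation), led by Mcam at -1.09. That call was lost with no filter and with a minimum of 0.1 FPKM (adjusted p = 0.272 and 0.201), where the median was 0.11, and with quantile normalization (adjusted p = 0.0556). Agtr1a, the angiotensin receptor gene, rose from 15.9 ± 1.35 to 57.8 ± 4.34 FPKM in a list of 5 that camera did not call (adjusted p = 0.616) and fry did (adjusted p = 0.0231).

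Stress and survival genes were mixed. In the oxidative stress list 4 of 17 rose, over all genes and adjusted over the list alone (adjusted p = 0.0476, and adjusted p = 0.564 with an estimated correlation), with the metallothionein gene Mt2A at 3.72 and the mitochondrial superoxide dismutase gene Sod2 at 2.45. That call was lost without NC replicate 1 or 2 or antagomiR replicate 1 (adjusted p = 0.0555, 0.134 and 0.0603), with median-ratio scaling (0.0673), with a minimum of 0.1 or 5 FPKM (0.0507 and 0.0538), without a trend (0.0634), by voom (0.0684) and with the leukocyte covariate (0.771). Without NC replicate 3, 9 rose. In the apoptosis list 6 of 18 rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.321 with an estimated correlation), led by the inhibitor Birc3 at 1.72. It was lost without NC replicate 1 or 2 (adjusted p = 0.0555 and 0.0776), with a minimum of 5 FPKM (0.155), by voom (0.0519) and with the leukocyte covariate (0.266). Of 23 unfolded protein response genes 10 fell and 1, Ddit3, rose, or 11 and 1 adjusted over the list alone (adjusted p = 0.000126, and adjusted p = 0.127 with an estimated correlation). Of 19 immediate early genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone (adjusted p = 0.00395, and adjusted p = 0.277 with an estimated correlation), a call lost with a minimum of 5 FPKM (adjusted p = 0.0905), where the median went from -0.22 to -0.07, and it was -0.12 without NC replicate 3. Of 17 WNT genes 6 fell and 2 rose, or 7 and 4 adjusted over the list alone (adjusted p = 0.0399, and adjusted p = 0.23 with an estimated correlation), a call lost without NC replicate 1 or 2 (adjusted p = 0.0506 and 0.0606), with median-ratio scaling and quantile normalization (0.0572 and 0.0775), with a minimum of 0.1 FPKM (0.0507), by voom (0.0531), with the leukocyte covariate (0.154) and by fry (0.171). Limma called 0 of 29 nuclear oxidative phosphorylation genes, with 2 at an unadjusted p under 0.05 and 0 by voom, but 4 rose without NC replicate 3, 1 rose without NC replicate 1, 1 fell with median-ratio scaling, and 2 rose and 2 fell with the leukocyte covariate. It called 0 of 13 mitochondrially encoded genes, with 1 at an unadjusted p under 0.05 and 1 by voom. Without NC replicate 3, 3 of these fell and camera called the list down (adjusted p = 0.0374), and 1 fell without antagomiR replicate 3.

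Camera did not call the other lists with all libraries and the main settings. Of matrix protease and inhibitor genes 9 of 17 rose and 2 fell, of hypoxia and glycolysis genes 10 of 22 rose and 2 fell, and of fatty acid oxidation genes 6 of 19 rose and 1 fell. The p53 list had 5 of 15 up and 3 down, heat shock 2 of 12 up and 2 down, autophagy and lysosome 5 of 22 up and 1 down, and actin cytoskeleton 4 of 23 up and 2 down. Mitochondrial biogenesis had 2 of 16 up and 1 down, and ribosomal proteins 1 of 40 up. The 40 ribosomal entries carried 33 symbols, so some symbols were counted more than once. The circadian clock had 2 of 16 up and 3 down, and microRNA machinery 4 of 16 up. Among markers of other cells, 3 of 15 cardiomyocyte genes rose and 2 fell, 2 of 4 endothelial genes rose and 1 fell, and 1 of 6 epicardial genes rose and 3 fell. Schwann and neuronal markers had 1 of 6 up and 2 down and adipocyte markers 1 of 3 up and 1 down. Erythroid markers had 0 tested members. Of these lists fatty acid oxidation was called up without NC replicate 3 (adjusted p = 0.0436) and ribosomal proteins, with a median of -0.06, without NC replicate 1 (0.0403). The protease list was called up with no filter, with a minimum of 0.1 FPKM and with quantile normalization (0.00583, 0.0126 and 0.012), the hypoxia list up with no filter and quantile normalization (0.0347 and 0.0145), and the clock list down with the latter (0.0477). Fry called the protease, hypoxia, endothelial and Schwann and neuronal lists (0.0113, 0.00828, 0.0059 and 0.00607).

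The tests below were chosen after the results were seen, apart from the counts of other splits. There are 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. For genes 1 of the 10, the real one, gave 3216 calls or more, and the highest other gave 1. Each other split puts NC and antagomiR libraries in both groups, so their difference widens the spread and few gene calls were set in advance. The gene counts therefore do not weigh against chance. For lists 1 of the 10, the real one, reached 21, and the highest other gave 18.

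The rise of inflammatory and interferon genes was set against a higher share of leukocytes in the antagomiR cultures. With leukocytes of unchanged make-up, that would raise the leukocyte markers alike and no gene by more. The markers did not rise alike, at 0.944 times the NC mean for Mrc1 and 11.05 times for Adgre1, so their median is a loose bound. Folds here and in the next comparison are ratios of group means with a pseudocount of 0.1, since log2(FPKM + 1) understates low genes. The median log2 fold of the inflammatory list exceeded that of the leukocyte list by 3.06 (permutation p = 0.00254 over genes, which are not independent), and by 2.72 without NC replicate 3 (permutation p = 0.0058). On the log2(FPKM + 1) scale it exceeded it by 1.4 (permutation p = 0.00516), but by 0.74 without NC replicate 3 (permutation p = 0.202). Of the 22 inflammatory members, 12 rose by more than every leukocyte marker with the pseudocount of 0.1, and 6 on the log2(FPKM + 1) scale. With the leukocyte covariate 20 of the 22 inflammatory members still rose, with a median of 2.43. The interferon list exceeded the leukocyte list by 0.74 (permutation p = 0.0155), but by 0.61 without NC replicate 3 (permutation p = 0.232), and on the log2(FPKM + 1) scale by 0.56 (permutation p = 0.0866) and 0.14 without NC replicate 3 (permutation p = 0.72). With the covariate 23 of its 26 members rose, with a median of 0.98, but most of the spread of the covariate within groups came from NC replicate 3. With the pseudocount of 0.1 the values argue against a higher share of leukocytes of unchanged make-up as the whole cause for the inflammatory list. On the log2(FPKM + 1) scale that outcome depends on NC replicate 3. For the interferon list the outcome depends on NC replicate 3 with the pseudocount of 0.1 too, so this comparison does not decide it. Of its 26 members 4 rose by more than every leukocyte marker with that pseudocount, and 1 without NC replicate 3. On the log2(FPKM + 1) scale 0 did, with or without NC replicate 3. Without that library the markers rose unequally, at 1.7 times for Mrc1, 6.25 for Lyz2 and 25.31 for Adgre1. These folds argue against leukocytes of unchanged make-up. A changed mix or state of the leukocytes, or a changed state of the fibroblasts, stays open for both. With 1 antagomiR sequence, effects of that oligonucleotide other than through miR-142-3p, on other RNAs or otherwise, were not tested and stay open.

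The fall of contractile and synthesis genes was set against dilution of fibroblast RNA by leukocyte RNA, which would lower the resident fibroblast markers as much. The median log2 fold of the contractile list differed from that of the resident markers by -1.05 (permutation p = 2e-05) and that of the cholesterol and fatty acid list by -1.25 (permutation p = 4e-05). On the log2(FPKM + 1) scale the differences were -1.04 and -1.2. With the pseudocount of 0.1 and 1 library left out they lay between -0.99 and -1.09 and between -1.16 and -1.36. The resident markers themselves rose, with a median of 0.48, which was known when this test was chosen. The differences therefore hold that rise as well as the falls, with medians of -0.57 and -0.77. Dilution alone would not raise fibroblast markers, so these values argue against it as the only change. How much of the falls came from dilution they do not tell. No other explanation was tested. Whether smooth muscle cells or pericytes became fewer stays open, since 5 of 9 tested markers of those cells fell but Steap4 rose and the list was not called with no filter.

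NC replicate 3 stood apart from NC replicates 1 and 2, and a mix with antagomiR material would place it the same share of the way to the antagomiR mean in each list. The median share was 82.7% for leukocyte markers and 3.4% for inflammatory genes, a difference of 0.793 as a fraction (permutation p = 1e-05, the smallest these permutations can give). This argues against such a mix as the whole cause. The median share was 3.3% for collagen processing, 5% for contractile and 5.2% for DNA replication genes, but -2.9% for resident fibroblast markers. A small mix beside another difference therefore stays open. The share was 27.4% for interferon genes, with 25 of 26 higher in NC replicate 3 than in both others, 30.3% for antigen presentation (7 of 7 higher), 25.8% for cholesterol and fatty acid synthesis and -11.7% for cell cycle genes. More leukocytes in that culture stays open, since it was found from the same markers. Whether the antagomiR cultures differ from NC in leukocytes for the same reason was not tested.

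A hypothesis was that reported miR-142-3p targets rise as a set. Their median log2 fold change lay at percentile 36.1 of 10000 random lists matched on mean expression, while fry called the list (adjusted p = 0.0248) with a mean of 0.198. That mean rests largely on Il6, at 2.10, which is also in the cytokine list. Of the 14 members 3 rose, 1 fell and 10 were not called. These data do not decide it.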
